A study of Mus musculus with 70 samples.

How the data were processed

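The samples are colon tissues of 70 male mice in 12 groups, defined by experiment, strain and diet, per the labels. Each mouse is a separate animal and a replicate of its group. Per the labels' protocols, the proximal part of the colon was divided between histology, gene expression and a backup sample. The RNA was extracted with Trizol, purified on columns and examined on a Bioanalyser, and food offered was adjusted each week to the intake of C57BL/6J mice on the control diet. The submitters' processing notes name limma, with no version given in the sources used here.

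The files analysed were 2 tables that describe the arrays of the gold and green experiments, with 36 rows each, and they hold no array intensities or ratios. The planned array analysis with limma, the gene lists fixed for it and their alternatives for background correction and normalization were therefore not run. The rule for named genes stated that no gene would be named as a result in that case.

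The tables' injury score and RNA integrity number are deposited as the authors recorded them, per the file headers, with no normalization. The injury score in the sample labels is on the same scale, in steps of 0.5 points, and its scoring scheme is not stated. The table column for dye incorporation is given with no unit, and was used only to compare arrays. There is no sequencing depth or signal over background behind these values, and their precision is limited by 4 to 6 mice per group.

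Rows of the tables were matched to mice by strain, fruit, diet and replicate number in the row's name. Of 72 rows, 69 matched a sample and 3 were not used. Of these, 2 rows of gold ethyl acetate C57BL/6J mice carried the same name, and 1 row, a green control C57BL/6J mouse, had a replicate number that no sample carries. In the gold ethyl acetate C57BL/6J group the row matched as replicate 5 is certain in its group and uncertain in its number. Table scores therefore rest on 4 mice in that group, 5 in the green C57BL/6J control group and 6 elsewhere. RNA integrity numbers were missing for 2 more mice, and rest on 5 in the gold aqueous Il10-/- and green ethyl acetate C57BL/6J groups.

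Groups were compared by the difference in mean score with two-sided exact permutation tests that enumerate every regrouping of the mice, of which there are 924 for 6 against 6, with a smallest possible p of 0.00216. Differences between strains or between experiments in extract minus control were tested by permuting diet within each part, so that the null is no diet effect in either. The 28 comparisons formed 6 families, and p-values were adjusted by the method of Benjamini and Hochberg within each (6 strain differences, 8 extracts against control, 4 aqueous against ethyl acetate, 4 between strains, 4 between experiments and 2 between control groups). Comparisons are said to pass at an adjusted p below 0.05. The extracts of a strain and experiment share their control mice, so their differences are not independent. The 95% intervals hold the shifts that the exact test did not reject, in steps of 0.05 points, and none was made for differences of differences. The tests were checked against SciPy and on simulated data: with no shift, 4.6% of 1000 simulated comparisons of 6 against 6 Il10-/- mice drawn from the table scores, and 4.5% drawn from the label scores, had an exact p below the threshold. RNA integrity and dye incorporation, with groups over 10, were compared by permutation tests with 100000 resamples in a family of 6, and tests within batches or of list order used 10000.

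The labels' score was chosen as the main record and the tables' score as the alternative before the data were examined, although the label scores themselves had been read when the tests were fixed. The other alternatives fixed at that point were mean ranks, medians, the replicate number as a block, the share of mice above the highest C57BL/6J control score by Fisher's exact test, and each mouse left out in turn. Mean ranks and left-out mice for the table scores, and shipment or day of tissue sampling as a block, were added after seeing the data, as were the comparisons of RNA quality and of the order of the scores. Offsets of 0 to 6 places were tried in the comparison of the score lists. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.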

Results

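Colon tissue was collected from 70 male mice in 2 feeding experiments, 1 with extracts of gold kiwifruit and 1 with extracts of green kiwifruit. Each experiment used Il10-/- mice, which lack the anti-inflammatory cytokine interleukin 10 and develop spontaneous inflammation of the intestine, and C57BL/6J mice as the strain without the deletion. The mice were 10.5 weeks old in the gold experiment and 12 weeks old in the green experiment. Within each strain, mice received the purified AIN-76A diet alone (control), the same diet with an aqueous extract at 5% of the diet, or the diet with an ethyl acetate extract at 0.11% of the diet. The 12 groups held 6 mice each, except that C57BL/6J mice on gold ethyl acetate extract and C57BL/6J mice on the green control diet numbered 5. The outcome analysed is a histology injury score of the colon, given per mouse in steps of 0.5 points, in which a higher value stands for more injury. How the score was built up is not given in the sources used here. Colon RNA of each mouse was also hybridised to a two-colour array, but no array intensities or ratios were analysed here, so no gene is reported.

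The injury score was recorded both in the sample labels and in the array annotation tables, and the 2 records differed. Of 69 mice with a score in both, 25 had equal scores. Equality was highest in gold C57BL/6J mice, at 15 of 16, and it was 0 of 18 in gold Il10-/- mice, 8 of 17 in green C57BL/6J mice and 2 of 18 in green Il10-/- mice. The largest gap for a single mouse was 9.0 points. When the mice were sorted by experiment, strain, diet (aqueous, control, ethyl acetate) and replicate number, the label scores equalled the table scores of a mouse a fixed number of places earlier. That number of places was 0 in gold C57BL/6J mice, 1 in gold Il10-/- mice, 2 in green C57BL/6J mice and 3 in green Il10-/- mice. With these offsets, 67 of 68 mice with a table score at that place had equal scores. The comparisons of diets and strains below are therefore given from both records, and each value names its record. The labels were set as the main record before the data were examined, and the tables as the alternative.

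**Figure D1:**
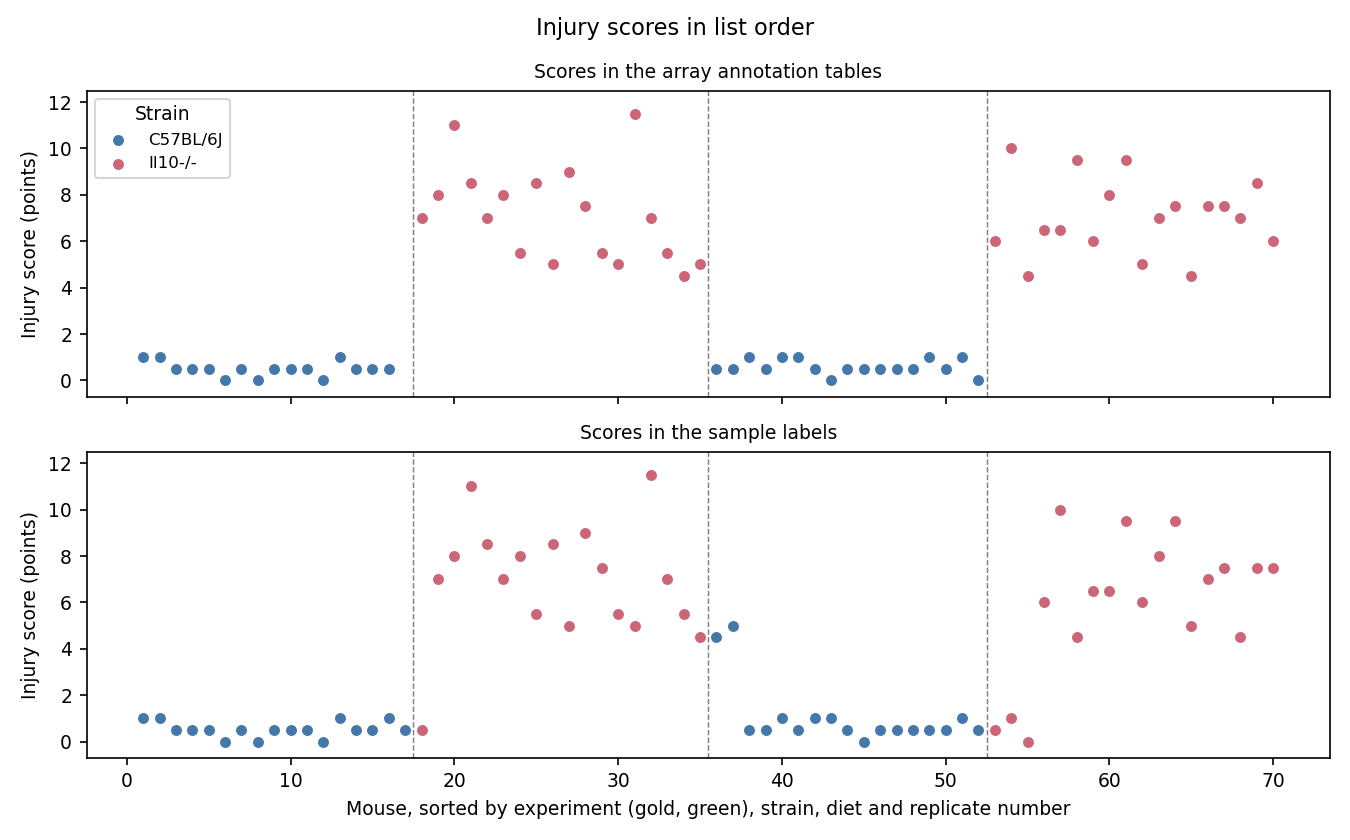
Colon injury score in points (vertical axis) of each mouse in sorted order (horizontal axis), from the array annotation tables (upper panel) and from the sample labels (lower panel), with colour marking the strain and dashed lines separating the strains of each experiment. In the lower panel 6 mice lie on the other strain's side of the gap between 1 and 4.5 points, and in the upper panel 0 do.

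Il10-/- mice had much higher colon injury than C57BL/6J mice. In the tables, the 36 Il10-/- mice scored 7.11 ± 1.83 points (SD, n = 36), between 4.5 and 11.5, whereas the 33 C57BL/6J mice scored 0.545 ± 0.315 (SD, n = 33), between 0 and 1. The strains did not overlap in that record. In the labels, the Il10-/- mice scored 6.43 ± 2.77 (SD, n = 36) and the C57BL/6J mice 0.809 ± 1.04 (SD, n = 34), with 4 Il10-/- mice at or under 1 point and 2 C57BL/6J mice above it. On the control diet, Il10-/- mice exceeded C57BL/6J mice by 6.92 points in the labels in the gold experiment (95% interval 5.0 to 8.25) and by 7.07 points in the green experiment (5.5 to 8.75), each with an exact permutation p of 0.00216 and an adjusted p of 0.00325. The table values were 6.5 points (5.0 to 8.25) and 6.77 points (5.25 to 8.3), each with an adjusted exact p of 0.0026. Within the 2 shipments of gold mice, the difference on the control diet was 8.0 and 5.83 points in the labels and 5.5 and 7.5 points in the tables.

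On the extract diets the strains also differed, with 1 exception that depended on the record. In the tables, all 6 strain comparisons passed the two-sided exact test, with differences from 5.79 to 7.67 points and adjusted p from 0.0026 to 0.00476. In the labels, 5 of 6 passed. The remaining comparison was the green aqueous diet, where the labels gave 3.67 ± 3.92 points in Il10-/- mice and 2.0 ± 2.14 in C57BL/6J mice (SD, n = 6 each). This difference of 1.67 points was within the spread of the mice (exact p = 0.418, 95% interval -2.25 to 5.5), and it was 0.4 points without Il10-/- aqueous replicate 5 (exact p = 0.764). The tables gave 7.17 ± 2.14 and 0.75 ± 0.274 points for the same groups, a difference of 6.42 points (exact p = 0.00216, adjusted p = 0.0026). The 5 label differences that passed no longer did so as differences in median, which were 5.0 to 7.25 points (adjusted exact p = 0.0753 each). On the control and ethyl acetate diets the strains did not overlap in the labels, so no regrouping gave a larger difference in median. The unadjusted exact p of 0.0606 and 0.0584 on the gold and green control diets was therefore the smallest possible, and neither could pass. With the day of tissue sampling as a block, the 5 label differences did not pass either, at 5.55 to 7.2 points (adjusted exact p from 0.05 to 0.0667). Of these, 4 of the 5 had the smallest unadjusted p that the mice per day allow. With that block, the table difference on gold ethyl acetate extract no longer passed (adjusted exact p = 0.0556), where its few mice per day allow no smaller p than 0.0556.

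**Figure D2:**
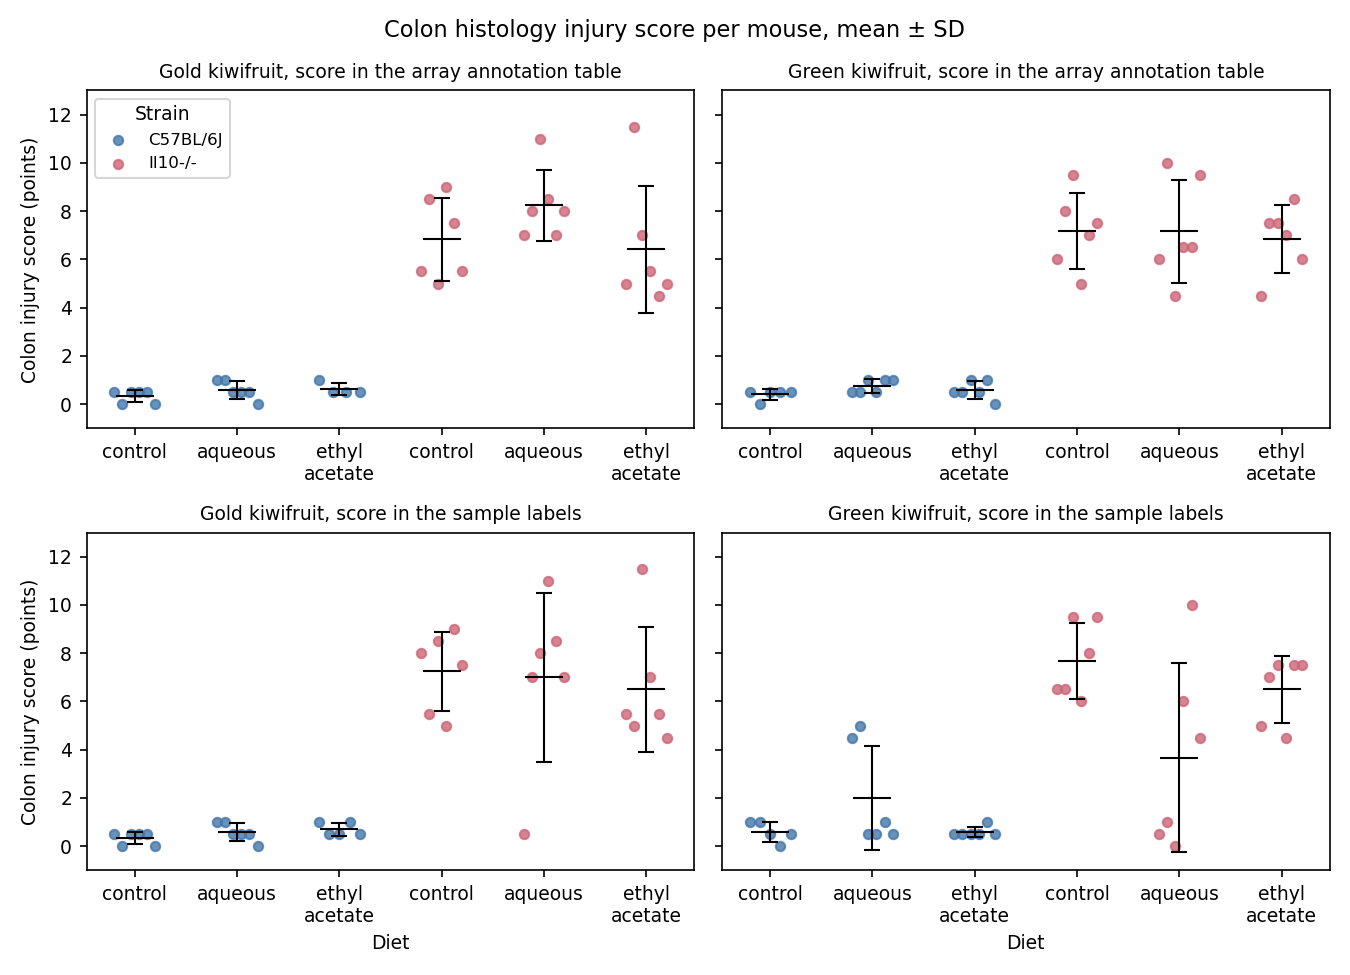
Colon injury score in points (vertical axis) by diet (horizontal axis) and strain (colour) in the gold and green experiments, with 1 point per mouse and black bars for mean ± SD (n = 4 to 6), from the array annotation tables (upper row) and the sample labels (lower row). Il10-/- mice lie between 4.5 and 11.5 in the upper row on every diet, and the mean that shifts most between the rows is that of green aqueous Il10-/- mice, from 7.17 to 3.67.

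The comparison of each extract with the control diet asks whether the extracts changed colon injury, above all in the inflamed strain. None of the 8 comparisons passed the two-sided exact permutation test after adjustment in either record, and at an unadjusted threshold the count was 0 of 8 in both. Ties left some of them unable to pass. In gold C57BL/6J mice the smallest possible p was 0.0758 for aqueous extract in both records. For ethyl acetate extract in these mice it was 0.152 in the labels and 0.1 in the tables. In green C57BL/6J mice on ethyl acetate extract it was 0.152 in the tables. In gold Il10-/- mice, the tables gave 6.83 ± 1.72 points on the control diet, 8.25 ± 1.47 on aqueous extract and 6.42 ± 2.63 on ethyl acetate extract (SD, n = 6 each). The aqueous group was 1.42 points above control (95% interval -0.75 to 3.5, exact p = 0.175; 0.867 to 1.85 points with any 1 mouse left out) and the ethyl acetate group lay 0.417 points below it, a difference of -0.417 (-3.15 to 2.65, exact p = 0.797). The labels gave differences of -0.25 (-4.0 to 2.8, exact p = 0.935) and -0.75 (-3.25 to 2.0, exact p = 0.606), so that the aqueous difference changed sign between the records. The label aqueous difference was 1.05 points (exact p = 0.329) without aqueous replicate 1, which had 0.5 in the labels and 7 in the tables. Without ethyl acetate replicate 3, which had a label score of 11.5, the label difference of that group was -1.75 (exact p = 0.0714, adjusted p = 0.286). The table difference was -1.43 without ethyl acetate replicate 2, which held the 11.5 there (exact p = 0.149), and 0.0167 without control replicate 4. Within shipments the table differences were 2.17 and 0.667 points for aqueous extract and -1.0 and 0.167 points for ethyl acetate extract, and the label differences were -0.167 and -0.333 points, and -2.5 and 1.0 points. With the day of tissue sampling as a block, the table differences were 2.54 (exact p = 0.0833) and -1.85 points (exact p = 0.111), and the label differences were -0.26 (exact p = 0.889) and -1.96 points (exact p = 0.0556). For ethyl acetate extract, each p was the smallest that the mice per day allow. For aqueous extract the smallest possible p was 0.0556 in both records, so neither blocked comparison could pass.

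In green Il10-/- mice the record mattered most. The tables gave equal means of 7.17 points on the control diet (SD 1.57, n = 6) and on aqueous extract (SD 2.14, n = 6), with a 95% interval of the difference from -2.5 to 2.5 points. The labels gave 7.67 ± 1.57 on the control diet and 3.67 ± 3.92 on aqueous extract (SD, n = 6 each), a difference of -4.0 points (-7.75 to 0, exact p = 0.0628, adjusted p = 0.502). Without the aqueous mouse of replicate 5, which had the highest label score of its group at 10.0, the label difference was -5.27 points and passed the threshold (exact p = 0.00433, adjusted p = 0.0346). The aqueous mice kept there include replicates 1, 2 and 3, at 0.5, 1 and 0 points in the labels and at 6, 10 and 4.5 in the tables. Their label scores equalled the table scores of green ethyl acetate C57BL/6J mice 3 places earlier in the sorted list. The ethyl acetate group differed from control by -0.333 points in the tables (-2.25 to 1.5, exact p = 0.779) and by -1.17 points in the labels (-3.25 to 1.0, exact p = 0.236). With the day of tissue sampling as a block, the aqueous difference was -0.464 points in the tables (exact p = 0.8) and -3.16 in the labels (exact p = 0.267), and the ethyl acetate difference was -0.574 (exact p = 0.58) and -1.35 points (exact p = 0.205). For aqueous extract in the labels, the mice per day allowed no p below 0.0667, so that blocked value could not pass. With groups of this size, effects near or even above the spread of the mice would often be missed. In simulated comparisons of 6 against 6 Il10-/- mice, the exact test without adjustment called 34.6% of shifts of 2 points and 91.3% of shifts of 4 points with scores drawn from the tables, and 21.1% and 57.5% with scores drawn from the labels. The label scores include 4 Il10-/- mice at or under 1 point, which the tables place at 4.5 or above. Shifting such mice down gives values below 0, which neither record holds. The label percentages therefore hold only for that record taken as it stands.

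In C57BL/6J mice scores stayed near the bottom of the scale on most diets. Table means were 0.333, 0.583 and 0.625 points on gold control, aqueous and ethyl acetate diets, and 0.4, 0.75 and 0.583 points on the green ones. All 4 extract groups had means above their control in the tables, by 0.183 to 0.35 points, and none of these differences passed the exact test (lowest exact p = 0.121). The label differences in gold mice were 0.25 points for aqueous extract (exact p = 0.394) and 0.367 points for ethyl acetate extract (exact p = 0.152), and in green mice -0.0167 points for ethyl acetate extract (exact p = 1). With shipment as a block, gold ethyl acetate extract was 0.5 points above control in the labels, the same in both shipments (exact p = 0.0375, adjusted p = 0.15). That value leaves out ethyl acetate replicate 6, whose shipment is not known, and rests on 4 ethyl acetate mice, among them replicate 5 with its uncertain number. In the tables it was then 0.389 points above control, with 0.5 and 0.333 points within shipments (exact p = 0.05, adjusted p = 0.2). Each of these p-values is the smallest that the ties and group sizes allow. With scores of 0, 0.5 and 1 in nearly all mice, ties limited the tests, and the smallest p possible for gold ethyl acetate extract against control was 0.1 in the tables. In the labels, green aqueous C57BL/6J mice averaged 2.0 ± 2.14 points (SD, n = 6) against 0.6 ± 0.418 in controls (SD, n = 5), a difference of 1.4 points (95% interval -0.55 to 4.0, exact p = 0.335) that was 0.8 points without aqueous replicate 2. The labels placed 2 of these mice at 4.5 and 5.0 points, and the tables placed the same mice at 0.5.

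Aqueous and ethyl acetate extracts were fed at different percentages of the diet, so their comparison is one of diets as fed and not of equal doses. None of the 4 comparisons passed the exact test in either record, adjusted or not. In the labels of green C57BL/6J mice ties allowed no p below 0.0606. The largest table difference was in gold Il10-/- mice, where aqueous extract exceeded ethyl acetate extract by 1.83 points (95% interval -1.0 to 4.25, exact p = 0.206). This value depended on a single ethyl acetate mouse, replicate 2, with a table score of 11.5. Without it the difference was 2.85 points (exact p = 0.00649, adjusted p = 0.026). Within the shipments, with all mice, the difference was 3.17 and 0.5 points. In the labels the same comparison gave 0.5 points (-4.0 to 4.0, exact p = 0.829). With the day of tissue sampling as a block, it was 3.13 points in the tables (exact p = 0.111) and 2.75 in the labels (exact p = 0.333), each the smallest p that the 2 shared days allow. In green Il10-/- mice the difference was 0.333 points in the tables (-2.0 to 2.65, exact p = 0.816) and -2.83 in the labels (-6.75 to 1.25, exact p = 0.134). In C57BL/6J mice it was -0.0417 points in gold (exact p = 1) and 0.167 points in green (exact p = 0.675) in the tables, and -0.117 (exact p = 0.675) and 1.42 points (exact p = 0.303) in the labels, where the green value was 0.817 points without aqueous replicate 2. Green Il10-/- mice on these diets shared 1 day of tissue sampling. On that day the difference was -1.33 points in the tables, against the direction with all mice, and -3.5 in the labels (exact p = 0.3 each). The mice of that day allowed no p below 0.1, so neither value could pass.

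Whether an extract acted differently in the strains was tested as the difference between Il10-/- and C57BL/6J mice in extract minus control, with diet permuted within strain. None of 4 comparisons passed after adjustment in either record. For green aqueous extract the labels gave -5.4 points (exact p = 0.0155, adjusted p = 0.0621), which was the only one of the 4 to pass without adjustment, and the tables gave -0.35 points (exact p = 0.747). The label value passed the threshold when 1 of 4 particular mice was left out, with differences of -6.67 without Il10-/- aqueous replicate 5 (adjusted exact p = 0.00652) and -5.7 without C57BL/6J aqueous replicate 3, 4 or 6 (adjusted exact p = 0.046 each). Each of these left-out values keeps the green aqueous Il10-/- mice at 0.5, 1 and 0 points in the labels, which the tables place at 6, 10 and 4.5. The other label values ran from -1.15 to -0.5 points. The gold ethyl acetate value went from -1.12 to -2.12 points without Il10-/- ethyl acetate replicate 3 (exact p = 0.0265, adjusted p = 0.0531). In the tables it went from -0.708 to -1.73 points without Il10-/- ethyl acetate replicate 2 (exact p = 0.0719, adjusted p = 0.288). All 4 table values lay between -0.708 and 1.17 points.

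Green and gold extracts did not differ detectably in their effect on injury. The difference between green and gold in extract minus control was largest for aqueous extract in Il10-/- mice, at -1.42 points in the tables (exact p = 0.358) and -3.75 in the labels (exact p = 0.152), and none of the 4 comparisons passed the exact test in either record. With any 1 mouse left out, these values ran from -1.98 to -0.867 points in the tables and from -5.05 to -2.95 in the labels. Control-diet mice of the 2 experiments were close. Green minus gold was 0.333 points in Il10-/- mice (95% interval -1.75 to 2.5, exact p = 0.792) and 0.0667 points in C57BL/6J mice (-0.25 to 0.35, exact p = 1) in the tables, and 0.417 (exact p = 0.723) and 0.267 points (exact p = 0.394) in the labels. Ties allowed no p below 0.0606 for the C57BL/6J controls in the tables, so that comparison could not pass. The experiments also differed in the age of the mice and in the days of tissue sampling, so fruit cannot be separated from age or day in any of these values.

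The array annotation gave RNA integrity numbers, a scale of RNA intactness that ends at 10, and these were higher in the inflamed strain. In the gold experiment they averaged 9.89 ± 0.139 in Il10-/- mice (SD, n = 17) and 9.49 ± 0.418 in C57BL/6J mice (SD, n = 16), a difference of 0.407 (permutation p = 0.00058, adjusted p = 0.00174). In the green experiment they averaged 9.76 ± 0.318 (SD, n = 18) and 9.41 ± 0.253 (SD, n = 16), a difference of 0.343 (permutation p = 0.00153, adjusted p = 0.00306). The highest value of 10 was reached by 18 of 35 Il10-/- RNAs and 4 of 32 C57BL/6J RNAs. Within days of RNA extraction the mean difference was 0.374, and Il10-/- RNA was higher on 8 of 9 days that held both strains. Diet made no detectable difference, since 0 of 8 comparisons of extract with control passed the exact test at an adjusted or unadjusted threshold (lowest exact p = 0.188). Dye incorporation, whose unit is not given, did not differ detectably between strains (15.8 against 14.5, permutation p = 0.421, in gold and 11.8 against 11.4, permutation p = 0.404, in green). It was higher in the gold experiment, at 15.2 ± 4.55 (SD, n = 34), than in the green experiment, at 11.6 ± 1.55 (SD, n = 35), with a permutation p of 1e-05, the smallest that 100000 permutations can give.

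**Figure D3:**
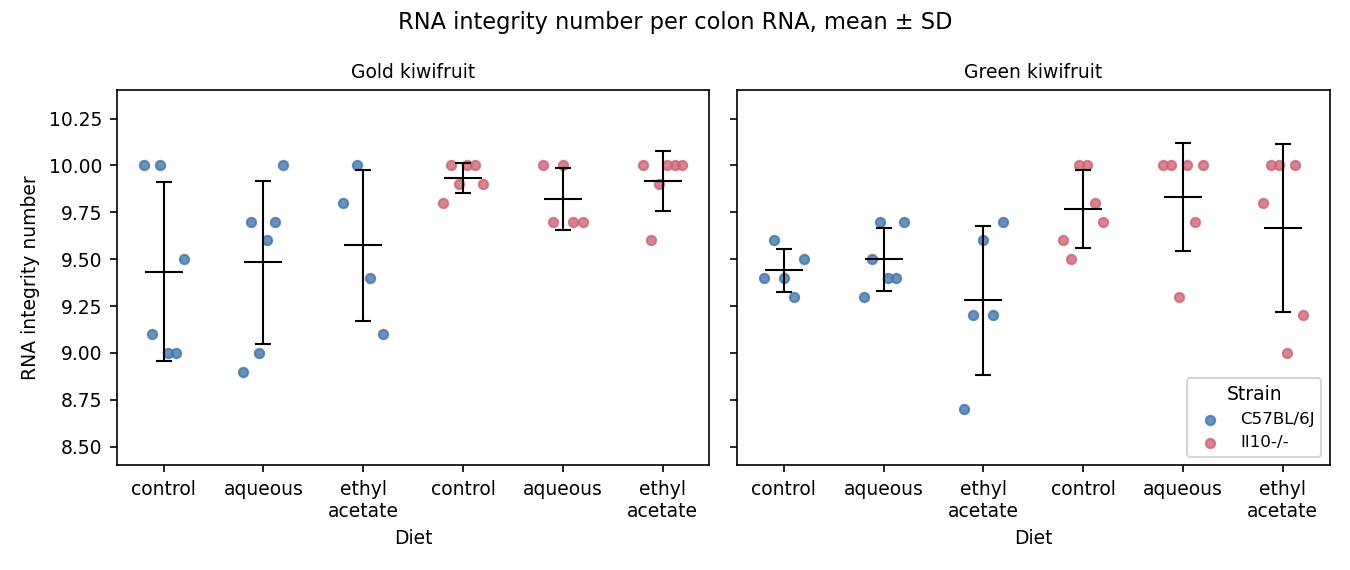
RNA integrity number (vertical axis, not starting at 0) of each colon RNA by diet (horizontal axis) and strain (colour) in both experiments, with black bars for mean ± SD (n = 4 to 6). Il10-/- RNAs average 9.89 and 9.76 in the gold and green experiments and C57BL/6J RNAs 9.49 and 9.41.

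Within each experiment, slides and hybridisation days held several groups, whereas 0 days of tissue sampling, RNA extraction or hybridisation and 0 scan sessions held mice of both experiments. Each experiment used 9 slides of 4 arrays, and no slide carried the same group on more than 1 of its matched arrays. All 6 groups of an experiment had arrays on every hybridisation day, of which there were 3 in the gold and 2 in the green experiment. They were not always evenly divided, with up to 3 arrays of a gold group and up to 5 of a green group on 1 day. All 69 matched arrays carried the mouse RNA in Cy3 and a common reference RNA in Cy5, with no dye swap. The gold arrays were scanned in 1 session, 26 of them 2 times and 8 of them 3 times, and the green arrays in 3 sessions, 1 time each. Gold mice came in 2 shipments and green mice in 1. Il10-/- mice of the later gold shipment scored 7.94 ± 2.26 points in the tables (SD, n = 9) and those of the earlier one 6.39 ± 1.58 (SD, n = 9), a difference of 1.56 points that did not pass the exact test (p = 0.125); this comparison was made on the table scores alone. A remark on slide loading stood beside 6 green arrays, 3 of each strain.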

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

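The test of exchanged labels was written before the table scores were seen; the tests of exchanged mice, of a displaced list and of a diet effect were chosen after the result was seen.

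In the labels, the effect of green aqueous extract differed between the strains by -5.4 points (exact p = 0.0155, adjusted p = 0.0621), since 2 C57BL/6J mice on that diet scored 4.5 and 5.0 and 3 Il10-/- mice scored 0.5, 1 and 0. A gold aqueous Il10-/- mouse at 0.5 belongs to the same pattern, which makes 6 mice on the other strain's side of the scale. Mice of the 2 strains exchanged for each other are argued against by the tables, where 0 of the 6 had a mouse number in the other strain's range and 0 had a score on its side. Both counts were 0 over all 69 matched mice, so they do not single out the 6. Rows were matched by the strain in their name, so exchanged labels that touched the label scores alone cannot show there. They stay open. All 6 had another score in the tables, and so did 38 of the 63 other mice (Fisher's exact test, p = 0.0799). This test cannot decide, since the 6 were picked for label scores on the other strain's side, where 0 table scores lie. A score list displaced by 1 to 3 mice in 3 of the 4 blocks gave 52 equal scores of 52 in those blocks, against 10 with no displacement, and 67 of 68 with the block that is not displaced. In each of the 3 displaced blocks 10000 permutations of the scores gave a smallest possible p of 1e-04. All 6 mice stand at the start of their strain in the sorted list, and 5 of the 5 with a table score at the displaced place had that score. An effect of the aqueous diet as large as in the labels is argued against by the tables, whose intervals exclude the label differences. The lower bound is -2.5 points in green Il10-/- mice against -4.0, and the upper bound is 0.75 points in green C57BL/6J mice against 1.4. Smaller effects stay open, since these intervals run from -2.5 to 2.5 and from 0 to 0.75 points. The arguments against exchanged mice and a diet effect assume that the tables hold the right records. The order of the scores argues against correct labels beside a displaced list in the tables, for the mice of this pattern. By label score 6 mice lie on the other strain's side, all at the start of their strain, and by table score 0 mice do. For 5 of them the label score equals the table score of a mouse of the other strain, 2 or 3 places earlier. For the 2 green C57BL/6J mice, at 4.5 and 5 points, it is a mouse of the other experiment. These are gold Il10-/- mice on ethyl acetate extract, replicates 5 and 6. The gold and green tables are separate, so a displacement within either table alone could not carry scores between the experiments. No other record used here settles which list is right. A displaced list in the labels remains a hypothesis, found and tested on the same data.

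Of 48 groups and measures tested for a mouse far from the rest of its group, 6 had one. The 2.4 that chance would give holds for untied values and independent tests. Tied scores and 2 records of the same mice meet neither condition, so no excess over chance can be read from it. The gold ethyl acetate Il10-/- group had a highest score of 11.5 with the next at 7.0, under replicate 2 in the tables and replicate 3 in the labels. That table mouse also had the lowest RNA integrity number of its group, 9.6, with the next at 9.9. The other 3 are single half-point steps in groups whose remaining mice tied: 1 in the labels in a green ethyl acetate C57BL/6J mouse with the rest at 0.5, 1 in the tables in a gold ethyl acetate C57BL/6J mouse with the rest at 0.5, and 0 in the tables in a green control C57BL/6J mouse with the rest at 0.5.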

How the results depend on the processing

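Table scores under mean ranks or with a mouse left out, and shipment or sampling day as a block, were chosen after seeing the data. Of the 28 comparisons, 21 kept their direction and their side of the threshold when the table score replaced the label score. The green aqueous strain difference passed at 6.42 points, and 5 differences that passed in neither record turned: aqueous minus control in gold Il10-/- mice (1.42), ethyl acetate minus control in green C57BL/6J mice (0.183), aqueous minus ethyl acetate in green Il10-/- mice (0.333), the gold aqueous effect between strains (1.17) and the ethyl acetate effect between experiments in Il10-/- mice (0.0833). Aqueous minus control in green Il10-/- mice went from -4.0 to 0. Mean ranks of label scores kept 25 of 28, gave 0 for aqueous minus control in gold Il10-/- mice, and turned the ethyl acetate effect between experiments in Il10-/- mice (0.167 ranks) and the aqueous effect between experiments in C57BL/6J mice (-0.55 ranks); those of table scores kept 25 of 28, turned the gold aqueous effect between strains (-0.167 ranks), and gave -0.333 ranks for aqueous minus control (from 0 points) and 0 for aqueous minus ethyl acetate in green Il10-/- mice. Medians left the 5 label strain calls above the threshold, at an adjusted exact p of 0.0753, with 7.25, 7.0 and 5.0 points on gold control, aqueous and ethyl acetate and 6.75 points on green control and ethyl acetate. On the control and ethyl acetate diets no regrouping gives a larger difference in median, so this loss says nothing about stability there. Medians also gave 0 for 8 differences that did not pass, kept 13 of 28, and turned the ethyl acetate effect between experiments in Il10-/- mice (2.25) and the Il10-/- control difference between experiments (-0.5). The share of mice above the highest control score turned aqueous minus ethyl acetate in gold Il10-/- mice (-16.7 percentage points) and was 0 in 3 of 12 comparisons; nearly all Il10-/- mice lie above that score, so it says little about stability. The cause was not tested for these turns, all of differences that did not pass.

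Replicate numbers are not known to pair the mice: same-numbered mice of 2 groups deviated together (r over 0.1) in 8 of 15 pairs of groups in gold and 6 of 15 in green by label score, and in 8 of 15 in each by table score. With the number as a replicate block, the 5 label strain differences of 6.92, 6.42 and 5.7 points in gold and 6.7 and 5.92 points in green had an adjusted exact p of 0.075, where 5 or 6 pairs allow few sign changes, and no other call changed (ethyl acetate minus control in green C57BL/6J mice went to 0). On the gold aqueous diet the unadjusted exact p was 0.0625, against 0.03125 for the 6 pairs on the gold control diet. Replicate 1 of the gold aqueous diet went the other way, at 0.5 in the Il10-/- and 1 in the C57BL/6J mouse. With shipment as a block all 9 gold comparisons kept their call in each record. With sampling day as a block, days with few mice limit the smallest p: the same 5 label differences were 6.97, 7.2, 5.55, 6.78 and 6.0 points (adjusted exact p 0.05 to 0.0667), and of the table's 6 only gold ethyl acetate was lost (5.77 points, adjusted exact p = 0.0556). It gave 0 in the labels for ethyl acetate minus control in green C57BL/6J mice. In the tables it turned aqueous minus ethyl acetate in gold C57BL/6J (0.0385) and green Il10-/- mice (-1.33), and gave -0.464 for aqueous minus control in green Il10-/- mice (from 0).

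With each mouse left out, no strain difference changed its call in 70 label and 69 table values; that of the green aqueous diet in the labels ranged from 0.4 to 2.4 points. Other label differences that changed sign or call, or reached 0, ranged from -1.05 to 1.05 (aqueous minus control) and -0.3 to 1.8 (aqueous minus ethyl acetate) in gold Il10-/- mice, -5.27 to -3.27 (aqueous minus control, green Il10-/-), -0.167 to 0.0833 (ethyl acetate minus control, green C57BL/6J), -0.2 to 0 (aqueous minus ethyl acetate, gold C57BL/6J), -1.3 to 0.8 and -6.67 to -4.67 (aqueous effect between strains, gold and green), -0.817 to 0.583 (ethyl acetate effect between experiments, Il10-/-) and -0.0333 to 0.767 (Il10-/- controls between experiments). The calls gained were those without green aqueous Il10-/- replicate 5 (-5.27 against control, -6.67 between strains) or C57BL/6J aqueous replicate 3, 4 or 6 (-5.7 between strains). Table differences ranged from 1.28 to 2.85 (aqueous minus ethyl acetate, gold Il10-/-, passing without ethyl acetate replicate 2), -0.125 to 0.0833 and -0.233 to 0.867 (the same, gold C57BL/6J and green Il10-/-), -1.43 to 0.0167 and -0.767 to 0.133 (ethyl acetate minus control, gold and green Il10-/-), -0.917 to 0.183 (green aqueous effect between strains), -0.0167 to 0.183 (aqueous effect between experiments, C57BL/6J), -0.208 to 0.0167 and -0.35 to 1.1 (ethyl acetate effect between experiments, C57BL/6J and Il10-/-), -0.567 to 0.533 (aqueous minus control, green Il10-/-, 0 with all mice), and -0.133 to 0.767 and 0 to 0.167 (Il10-/- and C57BL/6J controls between experiments). Differences that kept sign and call but changed over 1.5-fold in size ranged, in the labels, from -1.75 to -0.35 and -1.5 to -0.767 (ethyl acetate minus control, gold and green Il10-/-), 0.8 to 1.7 and 0.817 to 1.72 (aqueous minus control and minus ethyl acetate, green C57BL/6J), -2.12 to -0.717 and -1.48 to -0.75 (ethyl acetate effect between strains, gold and green), 0.55 to 1.45 (aqueous effect between experiments, C57BL/6J) and 0.167 to 0.417 (C57BL/6J controls between experiments). In the tables they ranged from 0.867 to 1.85 (aqueous minus control, gold Il10-/-), 0.167 to 0.333 and 0.0833 to 0.3 (ethyl acetate minus control, gold and green C57BL/6J), 0.05 to 0.25 (aqueous minus ethyl acetate, green C57BL/6J), 0.617 to 1.6 (gold aqueous effect between strains), -1.73 to -0.275 and -0.95 to -0.05 (ethyl acetate effect between strains, gold and green) and -1.98 to -0.867 (aqueous effect between experiments, Il10-/-). The array alternatives were not run, since no array values were analysed here.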

Other observations

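All tests in this part were chosen after the result was seen. RNA integrity numbers were higher in Il10-/- than in C57BL/6J colons in both experiments, by 0.407 and 0.343. The day of RNA extraction is argued against as the cause, since within days the difference was 0.374 over 65 RNAs, against 0.375 for the mean of the experiments (strain permuted within days, p = 1e-04, the smallest that 10000 permutations can give). The day of tissue sampling is argued against likewise, with 0.38 within days and Il10-/- RNA higher on 9 of 9 days (permutation p = 1e-04, again the smallest possible). Among Il10-/- mice, the relation of integrity to the table's injury score was open: r was -0.446 (permutation p = 0.0755, adjusted p = 0.144) and rho -0.237 (permutation p = 0.356, adjusted p = 0.356) in the 17 gold mice, with r = -0.0545 without the 2 most extreme RNAs, so that the gold relation rests on those. In the 18 green mice r was 0.361 (permutation p = 0.144, adjusted p = 0.144), rho 0.395 (permutation p = 0.105, adjusted p = 0.211) and r without the 2 most extreme RNAs 0.433. Pooled within experiments, r was 0.0932, and whether the degree of injury or another feature of the strain may set the integrity number cannot be told apart, since injury and strain go together and the number ends at 10.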
